A study of Forsythia suspensa with 2 samples.

How the data were processed

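The study measured polyadenylated RNA in 1 flower and 1 leaf sample of Forsythia suspensa, an ornamental and medicinal shrub of the olive family. Per the labels, both tissues came from plants aged 2 years grown outdoors, and the libraries were made with a strand-specific kit after oligo(dT) selection and random-hexamer priming. Each tissue has 1 library, so there were no replicates and no estimate of the spread between samples.

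Reads were trimmed with Trimmomatic and quantified with RSEM, per the submitters' processing notes. The versions of both tools, the aligner, the assembler and the sequence set used as reference are not given in the sources used here. The transcript identifiers have the form used by de novo assemblies, in which a component, a locus within it and a transcript of that locus are numbered. For each of 81913 transcripts the authors deposited an expected count, which is RSEM's estimate of the fragments that came from the transcript. All expected counts were whole numbers in both libraries (0 transcripts with a fraction), so the counts show no division of fragments among transcripts. The deposited TPM values are the authors' counts divided by effective length and scaled to a common total. The deposited FPKM values are, as computed from the files, the counts per kilobase of effective length scaled to the library's total. For transcripts of at least 50 counts this formula gave the deposited FPKM to within 0.307% in flower and 0.311% in leaf. The series-wide FPKM table deposited by the authors held the same values as the per-library files for 81913 of 81913 transcripts in each tissue, with a tolerance of 0.005 FPKM. The deposited isoform percent was 0 or 100 throughout, because each of the 81913 gene identifiers holds 1 transcript. A gene as the files define it is therefore a single transcript, and the planned gene-level and isoform-level fits are the same fit. Read from the identifiers, the transcripts fall into 67948 assembly loci.

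The totals were 7442016 expected counts in flower and 7234013 in leaf. CPM denotes a count divided by its library total, with the total adjusted by the scaling factor in use, and multiplied by 1000000. Unscaled, a count of 1 is worth 0.134 CPM in flower and 0.138 CPM in leaf. A count of 0 allows up to 3 counts, which, also unscaled, is 0.403 CPM in flower and 0.415 CPM in leaf. Intervals are exact Clopper-Pearson 95% intervals. Intervals of shares of counts and of single-transcript ratios, and the floors, cover counting error only. Intervals of shares of transcripts treat transcripts as independent. PCR copies were not separated from independent molecules.

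Expected counts were rounded to whole numbers, which altered none, and scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). The factors were 1.02 for flower and 0.98 for leaf. The log2 ratio of flower over leaf was taken from edgeR's log CPM with a prior count of 2, among transcripts with a CPM of at least 1 in at least 1 library. With 1 library per tissue no test across samples was made, and transcripts were classed by a fixed rule of size, a ratio of at least 4-fold. The ratio of a named transcript carries an exact interval conditional on its total count. Transcripts found in 1 library alone had a CPM of at least 1 there and an expected count under 1 in the other. Similarity was the correlation of log2(CPM + 1) across transcripts. Isoform use was compared within loci of at least 2 transcripts and at least 20 counts in each library, by each transcript's share of the locus after division by effective length. This grouping by identifier was chosen after seeing the data. The other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the figures matplotlib 3.10.9.

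The ratio step was tested on simulated data of 81913 transcripts with 200 of them changed. The changed transcripts were drawn from those of at least 10 CPM over both libraries together, so recovery at lower abundance was not tested. The median recovered log2 ratio was 2.97 for a true value of 3, and 1.99 for a true value of 2. The corresponding values for decreases were -2.97 and -1.97. Of the transcripts simulated at 8-fold, 100% passed the 4-fold rule in either direction. Of those simulated at exactly 4-fold, 46% of increases and 40.0% of decreases passed. Counting error alone was simulated in 20 draws of both libraries from 1 common level per transcript.

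The alternatives were DESeq2 1.42.0 size factors, library totals, no minimum CPM, a minimum of 5 CPM, a prior count of 0.5, TPM, FPKM with a pseudocount of 1 or 0.1, and the series-wide table. Added after seeing the data were assembly loci, thinning flower counts to the leaf total, and removal of the 100 most abundant transcripts of each library. The named transcripts are the 2 in each direction with the largest log2 ratio among those with at least 10 CPM in the higher tissue. This rule, the 4-fold rule and the alternatives, other than those named as added, were fixed before the data were examined. The files do not pair transcripts with gene names, so gene lists for lignan, phenylpropanoid and other pathways, fixed beforehand, were not used here. Genome positions and sequences were also not used here.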

Results

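RNA abundance was profiled in the flower and the leaf of Forsythia suspensa, a shrub that blooms yellow and whose fruit is used in East Asian medicine. The series is concerned with genes of secondary metabolism in medicinal Forsythia species, and the comparison examined here asks which transcripts differed in abundance between flower and leaf. Each tissue was represented by 1 library, and the values below have no replicate check. The labels do not say whether both tissues came from the same plant or from pooled plants. The flower library held 7442016 expected counts and the leaf library 7234013, assigned to 81913 assembled transcripts. Transcript lengths ran from 224 to 13226 bases with a median of 449 and an N50 of 1307. Transcripts of at most 500 bases made up 54.4% of the set but received 4.80% of the flower counts and 4.37% of the leaf counts. The transcripts carry assembly identifiers without gene names, so the differences are described by abundance, length and locus.

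More of the assembled transcripts were seen in flower than in leaf. At least 1 count was assigned to 75214 transcripts in flower and to 66708 in leaf, and 316 transcripts had none in either library. A CPM of at least 1 was reached by 38255 transcripts in flower and 35547 in leaf. The median count per transcript was 6 in flower and 5 in leaf, so most transcripts were measured on few counts.

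The leaf counts were more concentrated in the 100 most abundant transcripts than the flower counts. The 100 most abundant transcripts took 21.3% of the leaf counts (95% interval 21.29 to 21.35) and 17.4% of the flower counts (17.39 to 17.44). At the very top the order was the other way round, with 6.94% of flower counts (6.92 to 6.95) and 6.27% of leaf counts (6.26 to 6.29) in the 10 most abundant transcripts. By TPM the 10 most abundant took 6.65% in flower and 6.81% in leaf, so that order turned with the unit. These intervals cover counting error only and do not include variation between plants. The most abundant flower transcript was 6387 bases long and took 2.52% of the flower counts and 0.242% of the leaf counts. The most abundant leaf transcript was 923 bases long and took 2.12% of the leaf counts and 0.239% of the flower counts. None of the 10 most abundant transcripts was shared between the libraries (0 of 10), and 21 of the 100 most abundant were. The number of transcripts that together held 50% of the counts was 1722 in flower and 1208 in leaf.

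**Figure D1:**
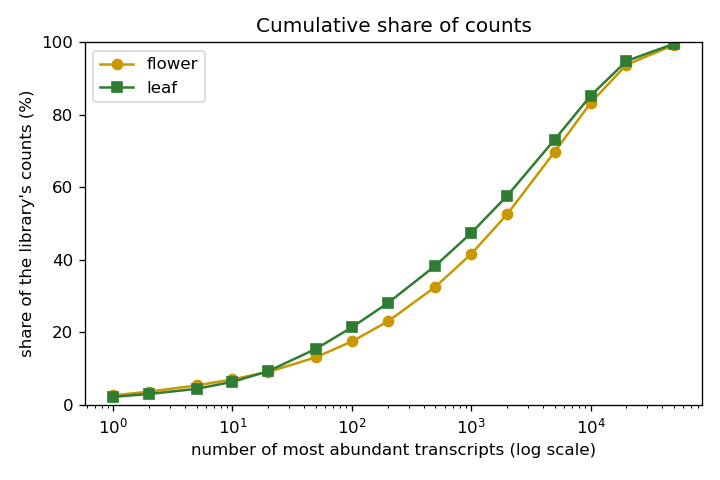
Cumulative share of each library's expected counts (vertical axis, percent) taken by its most abundant transcripts (horizontal axis, number of transcripts, log scale), for the single flower library (circles) and the single leaf library (squares). The 100 most abundant transcripts took 17.4% of counts in flower and 21.3% in leaf.

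Across all 81913 transcripts the abundances in flower and leaf were correlated, with a Pearson r of 0.83 and a Spearman rho of 0.64 on log2(CPM + 1). This is a correlation across transcripts, which are not independent replicates. Among the 44042 transcripts with a CPM of at least 1 in at least 1 library, 22656 (51.4%) lay within 2-fold of each other in flower and leaf, and 32841 (74.6%) within 4-fold.

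Transcripts at least 4-fold apart were more often higher in flower, when those with no count in the other library are included. Of the 44042 transcripts compared, 6889 (15.6%) were at least 4-fold higher in flower and 4312 (9.79%) at least 4-fold higher in leaf, so that flower-higher transcripts made up 61.5% of the calls (60.6 to 62.4). Intervals of such shares of transcripts are binomial over transcripts taken as independent, which transcripts of 1 locus are not, and are too narrow to that extent. The imbalance was larger at larger ratios. At 16-fold or more, 1612 transcripts were higher in flower and 463 in leaf, and at 64-fold or more the numbers were 341 and 44. When both libraries were simulated from 1 common level per transcript, counting error alone gave 20 to 48 flower-higher and 19 to 37 leaf-higher transcripts over 20 draws. The flower-higher set accounted for 26.8% of the flower counts and 2.03% of the leaf counts. The leaf-higher set accounted for 32.6% of the leaf counts and 4.67% of the flower counts. The flower-higher transcripts were the shorter ones, with a median length of 630 bases against 853, and the less abundant in their own tissue, with a median of 3.70 CPM against 7.03 CPM. With a minimum of 5 CPM the numbers were 2979 flower-higher and 2510 leaf-higher, and the flower-higher share was 54.3%.

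**Figure D2:**
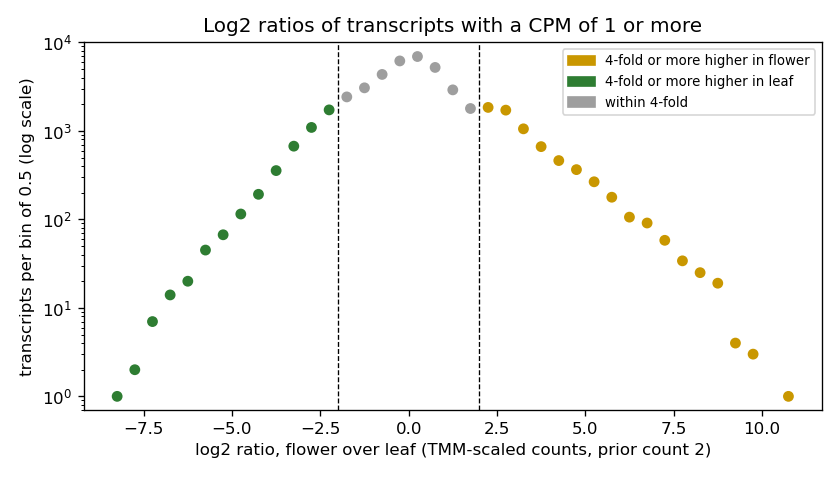
Distribution of the log2 ratio of flower over leaf (horizontal axis, TMM-scaled counts, prior count 2) over the 44042 transcripts with a CPM of at least 1 in at least 1 library, with the number of transcripts per bin on a log vertical axis. Dashed lines mark 4-fold, beyond which 6889 transcripts were higher in flower and 4312 in leaf.

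The direction of the imbalance differed between abundance bins. Among transcripts with a mean CPM under 5, flower-higher transcripts made up 67.0% of those at least 4-fold apart (65.9 to 68.1). The share was 55.7% at 5 to 10 CPM (52.9 to 58.6) and 52.2% at 10 to 50 CPM (49.9 to 54.4). It was 49.8% at 50 to 100 CPM (44.8 to 54.7) and 45.3% at 100 to 500 CPM (40.5 to 50.2). With TMM scaling the intervals of the bins from 10 to 500 CPM thus included 50%. Among the 180 transcripts with a mean of 500 CPM or more the flower-higher share was 33.9% (25.1 to 43.6), with 37 higher in flower and 72 in leaf. These most abundant transcripts were also the ones most often apart, as 60.6% of them differed at least 4-fold against 16.5% of those at 10 to 50 CPM. Scaled with DESeq2 size factors or with library totals, the share at 500 CPM or more was 37.5% and 36.3%. At 50 to 100 CPM it was 54.0% and 52.6% with those scalings, so the side of 50% on which that bin fell depended on the scaling. By length, the flower-higher share was 70.9% for transcripts of at most 500 bases (69.3 to 72.4), 63.2% for those up to 1000 bases, 52.4% up to 2000 bases and 45.5% above 2000 bases (42.1 to 48.9). Above 2000 bases it was 49.2% (45.8 to 52.7) with DESeq2 size factors and 47.5% (44.1 to 51.0) with library totals, so leaf-higher transcripts were the more numerous under each of these scalings, but whether the interval excluded 50% depended on the scaling.

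**Figure D3:**
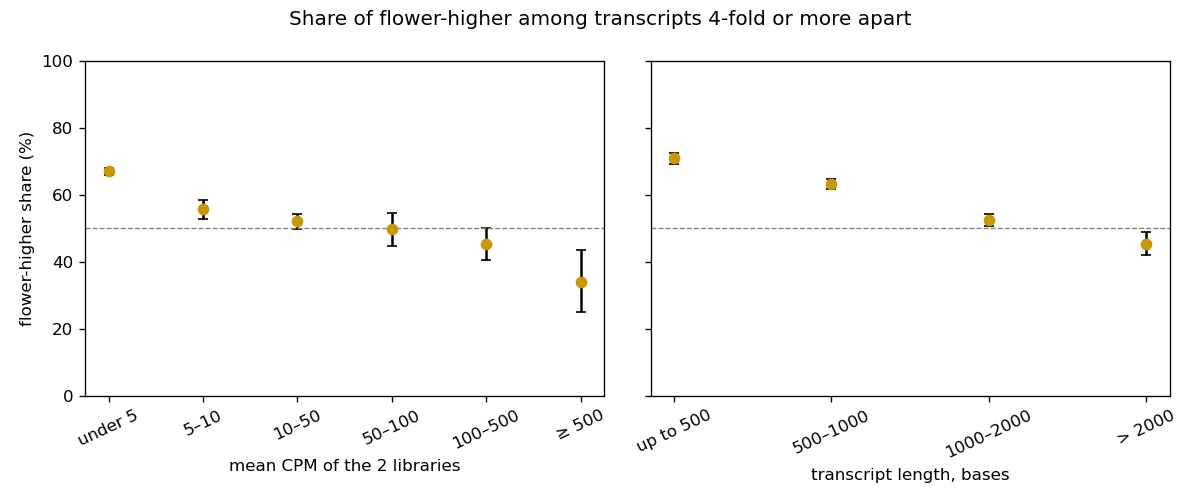
Flower-higher share (vertical axis, percent) of the transcripts at least 4-fold apart, by mean CPM of the 2 libraries (left) and by transcript length in bases (right). Points are shares, bars are exact 95% binomial intervals over transcripts taken as independent, and the dashed line marks 50%. The share was 67.0% under 5 CPM and 33.9% at 500 CPM or more, and 70.9% up to 500 bases and 45.5% above 2000 bases.

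Transcripts detected in 1 tissue alone were mostly flower transcripts. At a CPM of at least 1, 3727 transcripts were detected in flower with no count in leaf, and 816 in leaf with no count in flower. With the prior count of 2, every such transcript also passes the 4-fold rule. They thus made up 3727 of the 6889 flower-higher calls and 816 of the 4312 leaf-higher calls. Among the calls with a count in both libraries, leaf-higher transcripts were the more numerous. The excess of flower-higher calls therefore lay in transcripts with no leaf count. Transcripts detected in 1 tissue alone had median lengths of 506 bases (flower) and 469.5 bases (leaf), and rested on a median of 14 and 12 counts. The median of 449 bases over the whole assembly includes transcripts under the CPM minimum. Of the 44042 transcripts that met it, only 8635 were at most 500 bases long, so those seen in 1 tissue alone were short by comparison. They held 1.64% of the flower counts and 0.209% of the leaf counts. At 10 CPM or more, 278 transcripts were seen in flower alone and 22 in leaf alone, and at 50 CPM or more the numbers were 27 and 1. A count of 0 allows up to 0.415 CPM in leaf and 0.403 CPM in flower, before scaling, so absence from a tissue was not shown.

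Among transcripts of at least 10 CPM, those ranked highest by log2 ratio differed by more than 100-fold in scaled counts in both directions. The folds given here are ratios of scaled counts without a prior count, while the log2 ratios carry the prior count of 2 and are therefore smaller for transcripts with few counts in the lower tissue. TR22385|c0_g1_i1|c0_g1_i1, a transcript of 890 bases, had 6126 counts in flower and 2 in leaf, a ratio of 2876-fold (796 to 23749.9). Its log2 ratio with the prior count was 10.51, and 9.63 on the log2(TPM + 1) scale. TR32460|c0_g1_i1|c0_g1_i1, of 906 bases, had 77224 counts in flower and 74 in leaf, a ratio of 979.7-fold (780.3 to 1248). Its TPM was 13340 in flower and 13.6 in leaf. In the other direction, TR27564|c0_g1_i1|c0_g1_i1, of 1407 bases, had 1 count in flower and 741 in leaf, a leaf-over-flower ratio of 789-fold (141 to 31217). Its log2 ratio was -8.01 with the prior count of 2, -9.03 with a prior count of 0.5 and -6.21 on the log2(TPM + 1) scale, so the size of this difference rests on the setting. TR24605|c1_g1_i1|c0_g1_i1, of 755 bases, had 9 counts in flower and 2197 in leaf, a leaf-over-flower ratio of 260.02-fold (137 to 569). The intervals are conditional on each transcript's total count, and the wide ones reflect the 1 or 2 counts in the lower tissue. The transcripts were picked for their extreme ratios, and the intervals do not allow for that choice. Both leaf-higher transcripts belong to loci of 2 transcripts, so their counts could depend on how reads were assigned within the locus.

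The leading transcript of a locus often differed between the 2 libraries, but much of this also arose in draws of counting error alone. A large move in the leading transcript's share was rare. The identifiers placed 60747 transcripts in loci of their own, and 7201 loci held 2 or more transcripts. Of the 5754 such loci with at least 20 counts in each library, the most abundant transcript differed between flower and leaf in 1750 (30.4%). Draws with equal transcript shares in both tissues gave 1157 to 1302 such loci over 100 draws, fewer than the 1750 observed. In 55 loci the leading transcript differed and its share moved by at least 50 percentage points, where the draws gave 0 to 10. Of 6280 loci with at least 2 transcripts compared, 761 contained a transcript at least 4-fold higher in flower, 767 one at least 4-fold higher in leaf, and 15 contained both.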

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

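No replicate could be left out and no test across samples could be made, because each tissue has 1 library. No paired analysis was possible because each group holds a single sample. Choosing isoforms in place of genes altered nothing, since each gene identifier holds 1 transcript, and the gene-list alternatives were not run. Assembly loci, thinning and removal of abundant transcripts were added after seeing the data. None of the alternatives run reversed the overall flower excess. The named transcripts kept their direction under the 6 alternatives run for them (DESeq2 size factors, library totals, a prior count of 0.5, TPM, and FPKM with either pseudocount). However, the order of the tissues in the share of the 10 most abundant transcripts turned with TPM, and the flower-higher share at 50 to 100 CPM (49.8%) was 54.0% with DESeq2 size factors and 52.6% with library totals. The number of transcripts at least 4-fold higher in flower (6889) ranged from 6274 to 8012 under the alternatives that count transcripts, other than a minimum of 5 CPM, which gave 2979, and the number higher in leaf (4312) from 3550 to 5318, with 2510 at 5 CPM. Counted over 32629 assembly loci, 5843 were higher in flower and 3306 in leaf. At 5 CPM (24640 compared), flower-higher calls fell more. The flower-higher share of 61.5% was 63.4% with DESeq2 size factors, 62.5% with library totals, 60.6% with no minimum CPM, 54.3% with a minimum of 5 CPM, 58.7% with a prior count of 0.5, 63.9% with TPM, 64.4% with either source of FPKM at a pseudocount of 1, 59.4% at a pseudocount of 0.1, 63.9% over assembly loci and 64.6% with the most abundant transcripts removed and both libraries thinned to equal totals. That last setting lowered the totals, so that 48990 transcripts passed the CPM minimum, which also bears on its 8012 flower-higher transcripts. At a minimum of 5 CPM, transcripts seen in flower alone numbered 671 and in leaf alone 77. The correlation across transcripts was 0.73 (Pearson) and 0.68 (Spearman) after the CPM filter, and 0.85 and 0.57 over assembly loci; the cause was not tested. By TPM the 10 most abundant transcripts held 6.65% in flower and 6.81% in leaf, and the 100 most abundant held 17.3% and 20.7%. With at least 100 counts per library, 3564 loci in place of 5754 were compared. Of these, 28 in place of 55 switched their leading transcript by 50 points. The leading transcript differed in 966 (27.1%) in place of 1750 (30.4%). On the log2 scale TR27564|c0_g1_i1|c0_g1_i1 moved from -8.01 to -6.21 with TPM and -6.25 with FPKM at a pseudocount of 1, and TR22385|c0_g1_i1|c0_g1_i1 from 10.51 to 9.63 with TPM. Depth limits most the 22462 of 44042 compared transcripts whose mean was under 5 CPM.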

Other observations

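The patterns in this part were noticed in the same data on which they were tested. The tests of leaf RNA in the flower library and of pairs within loci were chosen after their results, or part of them, had been seen, and the others after the flower and leaf ratios but before their own results.

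Abundant leaf transcripts were seldom nearly missing from flower. Among 1549 transcripts of at least 100 CPM in leaf, 6 had an upper bound under 1% of their leaf level in flower. Among 1605 transcripts of at least 100 CPM in flower, 70 had an upper bound under 1% of their flower level in leaf. The leaf-higher set summed in flower to 14.3% of its level in leaf, and the flower-higher set in leaf to 7.57% of its level in flower, but both sets were chosen for their ratios, so these sums follow in part from that choice and do not measure a retained level. Leaf RNA mixed evenly into the flower library would keep every abundant leaf transcript at or above 1 common share, whereas 17 leaf transcripts had an upper bound under 1.43%, which is 0.1 of the summed level, and the lowest bound was 0.708%. This argues against an even admixture large enough to give the summed level, and a smaller admixture and a difference between the tissues stay open.

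More transcripts were at least 4-fold higher in flower than in leaf. The excess lay in transcripts with no count in leaf, which were 3727 of the 6889 flower-higher calls. Transcripts with no count in flower were 816 of the 4312 leaf-higher calls. Calls with a count in both libraries were more often higher in leaf. The difference in total counts does not account for the excess, since flower-higher transcripts were still 61.1% of the calls after flower counts were thinned to the leaf total. The totals were close (7442016 and 7234013), so thinning removed few counts. It does not bear on the number of independent molecules behind the counts. The larger weight of abundant transcripts in leaf was also examined. The share was 64.6% without the 100 most abundant of each library (179 transcripts removed) and with both libraries thinned to equal totals. In that setting 48990 transcripts were compared. TMM scaling, which already allows for such weight, was used with and without the removal, so the removal is a weak test of it. With library totals alone, without TMM, the share was 62.5%. Counting error around 1 common level per transcript supplied at most 1.13% of the excess over 20 draws. Both libraries were drawn from the same levels with similar totals, so a sizeable excess on 1 side could not arise. The result bounds the number of calls due to counting error and does not test their direction. The draws do not cover transcripts that differ in level, or noise beyond counting error such as PCR copies. A more varied set of expressed genes in flower, variation between the plants sampled (the labels do not say whether they were the same, single or pooled), and RNA of other organisms on the sampled tissue stay open and untested. The source of the sequence set used as reference is not given, so its bearing on the excess could not be tested either.

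The excess of flower-higher transcripts lay among short transcripts. A different fragment length (171 bases in flower and 178 in leaf, from the effective lengths) is a candidate cause, but with TPM, which corrects for it, at a pseudocount of 0.1, the flower-higher share of transcripts up to 500 bases was still 63.8%, against 46.1% above 2000 bases. These values change the pseudocount along with the unit. The count ratios corrected for effective length alone, with the prior count kept, gave 69.6% and 45.2%, against 70.9% and 45.5% uncorrected. Low abundance could explain much of the trend: the share was 15.7 percentage points higher for transcripts up to 1000 bases than for longer ones, and 6.14 points higher (bootstrap SE 1.35 over transcripts) within 7 bins of mean CPM. The bin under 1 CPM holds only 16 longer transcripts, and without it the difference was 5.89 points (SE 1.39). The difference did not go one way in all bins: the share was 44.0% for short and 51.6% for longer transcripts at 50 to 100 CPM, and 42.0% and 43.3% at 100 CPM or more. A difference of more than 2 SE thus remained within the bins, with an SE that treats transcripts as independent. It lay within 2 SE of the 5 points set beforehand as negligible. Whether length matters beyond abundance by more than that margin cannot be told here.

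One hypothesis concerned the assembly itself: transcripts of 1 locus, as their identifiers define it, may come from 1 gene or share reads, and would then have like ratios. Over 3607 pairs of transcripts of a locus with a mean of at least 5 CPM, the log2 ratios had a Pearson r of 0.89 (Spearman rho 0.85), above the highest of 1000 permuted pairings (0.06). Pairs from different loci of 1 component had an r of 0.62 over 1682 pairs, and pairs from neighbouring component numbers an r of 0.00068 over 4845 pairs. The loci with transcripts at least 4-fold apart in opposite directions, 15 of 6280, are therefore exceptions that a reader with the sequences could examine for distinct genes joined in 1 locus.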
